A study of Mus musculus with 8 samples.

How the data were processed

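CD8+ T cells that had infiltrated B16.SIY.dsRed tumors were profiled on a 1-colour Illumina mouse bead array. Per the labels and the series' design text, 10 female C57BL/6 mice received the tumor cells in both flanks, and the tumors were pooled on day 14. They were dissociated through a 50 µm filter, and lymphocytes were enriched on Ficoll. Cells were stained for viability, CD8a, CD4, CD3, 4-1BB, LAG3 and PD-1 and sorted into lysis buffer. Total RNA was labelled with Cy3 by a university genomics core, and the amplification method is not given in the sources used here. The titles give the sorted population and an experiment number for each of the 8 arrays, 2 for each of 4 populations. The replicates are 2 experiments of pooled mice, so p-values measure the spread between pools and not between single animals.

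The unnormalized probe intensities were deposited by the authors before any background subtraction, per the file headers and the values, where each array had its own median. Each came with a detection p-value from the scanner software, per the file headers. The software and its version are not given in the sources used here. The authors' normalized intensities, in the series' value table, were on a linear scale, and no source used here states how they were made. Their sorted values differed by at most 0.5 between arrays, their medians lay between 1.2 and 1.3 and some values were negative, as after background subtraction and quantile normalization. They were not centred by gene, and each array kept the rank order of its own unnormalized signals (rank correlation at least 0.9999). They were used as an alternative only.

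Of 25697 probes, 23978 had 1 gene symbol in the platform table, 0 had several and 1719 were not listed there. Of the listed symbols, 23962 were updated by gene identifier through RefSeq gene names of assembly GRCm38.p6, used for names only, and 16 were kept. Of the other probes, 1038 were named through their accession and 681 kept the name in the deposited table. This gave 17830 names. Gene positions are not given, since no genome build is named.

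Intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with negative controls inferred from the detection p-values and an offset of 16, and taken to log2. A gene with several probes was represented by the probe with the highest mean. Of 69 changes of named genes with another probe detected on at least 2 arrays, 23 had one whose change was under 0.5 times as large or the other way, 7 of them the other way. A gene was tested if its probe had a detection p under 0.05 on at least 2 of the 8 arrays, which kept 7893 genes and removed 9937. The offset compresses the changes of dim genes. Mean signals were lowest on the PD-1+ arrays, 123 and 90.9, and detected probes were brighter than undetected ones by a factor of 1.18 on PD-1+ array 2 to 1.79 on triple-negative array 1. The number of arrays limits the precision, and the median standard error of a log2 change was 0.448. The first 3 principal components held 30.0%, 23.3% and 19.6% of the variance. PD-1+ array 2 lay farthest out on the first (-71.2, the others -27.6 to 33.3) and PD-1+ array 1 on the third (-68.7, the others 1.63 to 15.1), so these 2 replicates stand apart from the other arrays and from each other.

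The 6 comparisons between populations were tested with limma's lmFit and eBayes over all 8 arrays, with 1 mean per population and no block (4 residual and 2.98 prior degrees of freedom). Adjusted p-values are by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and all tests were two-sided. An exact test of 2 arrays against 2 could not go below p = 0.333. A gene not detected on either array of a population has only a bound there, which depends on the normalization. Its fold is given as "at least" the brighter population's mean over the mean of the array floors, where a floor is the lowest detected signal of an array or the gene's own signal if that is higher.

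Gene lists were tested with camera of limma at a preset correlation of 0.01, adjusted over the 26 of 29 lists with at least 3 tested genes. Camera with an estimated correlation and limma's fry, which asks whether a list's genes move on balance in 1 direction without a comparison to other genes, were run beside it. For several lists the estimate lay below the preset, such as -0.00379 for naive and memory T cell genes, -0.0173 for the proteasome and -0.0458 for cholesterol synthesis. A call that such a list lost with the estimate does not show that correlation between its genes undid it. Counts adjusted over the list alone use the same limma p-values, adjusted within the list. The groups, tests, gene lists, most alternative settings and the rule for named genes were fixed before the data were examined.

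The rule named the genes of the sorting markers, the 10 highest and 10 lowest changes past the threshold in double-positive against triple-negative cells, and the 5 highest and 5 lowest in each other comparison. Both arrays of a population had to lie beyond both of the other. Where no gene passed, it took the 3 with the smallest p. From each list discussed it took up to 4 members that passed and up to 2 that did not, by size of change. The lists discussed were those called in a comparison, the receptor lists everywhere, and the transcription factor and anergy lists in double-positive against triple-negative cells, a choice made after the values were seen. Of the genes the rule takes, 1 is not reported here.

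The alternative settings were normexp with an offset of 50, no background correction, median scaling, the authors' normalized values, no detection filter, detection on all arrays, every probe tested separately, the experiment as a fixed or random block, a trended and robust prior, array weights, only the 4 arrays compared, a minimum log2 change of 1, and each array left out in turn. A fit without both PD-1+ arrays and gene lists without the genes of the sorting markers were added after the data were seen. The labels give the same experiment number to 1 array of each population. The number was treated as pairing the arrays only in the block settings and in differences within an experiment, since it names a shared experiment. The main fit did not use it and took all arrays as independent, so its p-values leave out any such pairing. The deviations of arrays with the same number correlated at 0.0920 to 0.222 across genes.

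The fits were tested on simulated data for double-positive against triple-negative cells, with 7893 genes, 200 of them changed, in 50 simulations. Limma recovered 0.507% of genes changed by a log2 of 1, 16.6% by 2 and 79.8% by 4, and called 0.0471% of the unchanged genes. The mean false share among calls was 5.23%. Without any change, 3 of 50 simulations had a call and 1 a called list. Camera called 100% of lists shifted by 1 and 1% of lists without a shifted gene. The simulated genes were independent of each other and had the same spread in every population. In the data the estimated correlation was 0.656 for the melanoma cell list, and the PD-1+ replicates agreed least. These rates therefore do not cover lists of correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.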

Results

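Gene expression was measured in CD8+ T cells sorted from tumors of B16.SIY.dsRed, a mouse melanoma line that carries the model antigen SIY and the red fluorescent protein dsRed. The tumors had grown for 14 days in female C57BL/6 mice. The sort used 3 surface receptors, the costimulatory receptor 4-1BB (gene Tnfrsf9) and the inhibitory receptors LAG3 (Lag3) and PD-1 (Pdcd1). It gave 4 populations: cells without any of the 3 receptors (triple-negative), cells with PD-1 but neither 4-1BB nor LAG3 (PD-1+), cells with LAG3 but not 4-1BB (LAG3+), and cells with both 4-1BB and LAG3 (double-positive). The labels do not give PD-1 for the LAG3+ and double-positive cells. Each population had 2 arrays, 1 from each of 2 experiments of pooled mice, and this number limits the precision of every value. The question, as the series title puts it, concerns dysfunctional CD8+ T cells within the tumor.

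In experiments 1 and 2, 9044 and 6933 of the 25697 probes were detected in triple-negative cells, 6404 and 5522 in PD-1+ cells, 8493 and 7282 in LAG3+ cells, and 8671 and 7339 in double-positive cells. Replicate arrays correlated across genes at r = 0.898 for triple-negative, 0.771 for PD-1+, 0.928 for LAG3+ and 0.934 for double-positive cells. The PD-1+ arrays had the fewest detected probes of each experiment and the lowest replicate correlation, and each stood apart from all other arrays on a principal component of its own (the first for array 2, the third for array 1). They correlated less with each other (0.771) than either did with any array of another population (0.778 to 0.853). Means over the PD-1+ arrays thus join 2 unlike profiles. After normalization, 7893 genes were tested. Values after ± are standard errors of the log2 change unless named otherwise, with 2 arrays per population. They use a spread per gene pooled over the arrays of all populations, so a gene has the same standard error in every comparison. The spread was not equal. The standard deviation of replicate differences across genes was 0.83 in triple-negative, 1.27 in PD-1+, 0.70 in LAG3+ and 0.67 in double-positive cells. The standard errors may thus be too small for changes with PD-1+ cells and too large for the others. A gene that was not detected on either array of 1 population is given as "at least" a fold, a bound that holds for the normalization used. A range beside an adjusted p covers all alternative settings, as do the medians given for a list where a setting moved its median over 3-fold or past 0, and "the block" is the experiment number. The 2 experiments are given apart where the median of a called list in 1 was over 3 times that in the other or of the other sign. The probe used for a gene was its brightest, and another detected probe is given where its change was under 0.5 times as large or the other way.

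The genes of the sorting markers were examined first. Cd8b1, the CD8 beta chain, averaged between 12.16 and 12.47 on the log2 scale in the 4 populations, and Cd3e, a chain of the T cell receptor complex, between 11.09 and 11.51. The smallest limma adjusted p over the 6 comparisons was 0.689 for Cd8b1, 0.636 for Cd3e and 0.564 for Cd4, which was detected on 2 arrays. Against triple-negative cells the Cd8b1 probe used differed by 0.18 ± 0.31 in LAG3+ and 0.18 ± 0.31 in PD-1+ cells, and another by -0.58 and -0.59. The Cd8a probe was detected on 0 of 8 arrays, so this transcript was not measured here. Lag3 averaged 4.48 in triple-negative, 8.67 in PD-1+, 9.19 in LAG3+ and 9.34 in double-positive cells, and passed the test against triple-negative cells in the other 3 populations. Tnfrsf9 averaged 4.94, 7.41, 7.63 and 8.90 in the same order and passed the test between double-positive and triple-negative cells. Pdcd1 was dim, averaged 4.16, 4.83, 4.97 and 5.10, and passed no comparison (smallest limma adjusted p = 0.393).

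**Figure D1:**
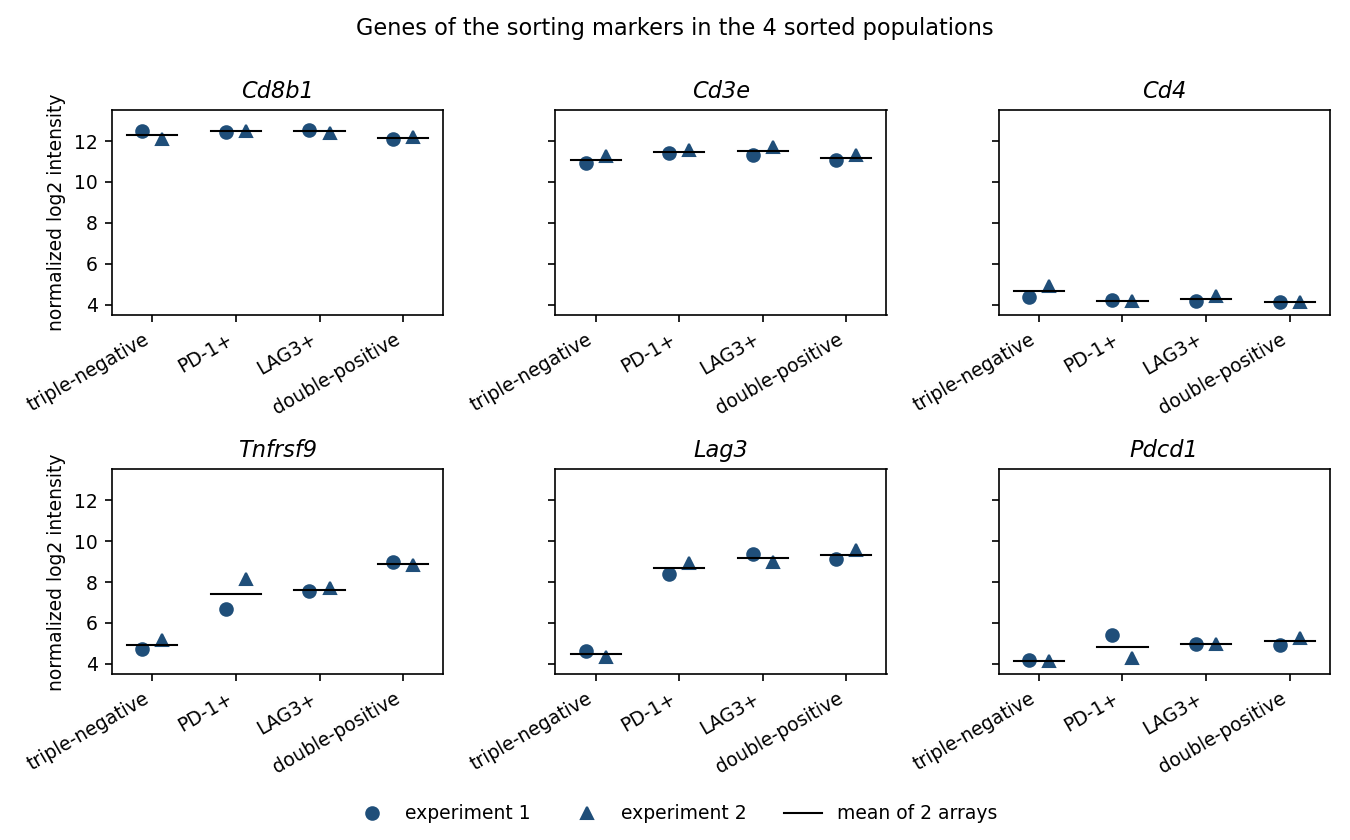
Normalized log2 intensity of the sorting-marker genes on each of the 8 arrays (circles, experiment 1; triangles, experiment 2; lines, means of 2 arrays). Lag3 averages 4.48 in triple-negative cells and between 8.67 and 9.34 in the other 3 populations.

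Double-positive cells were compared with triple-negative cells to describe the CD8+ T cells that carry both 4-1BB and LAG3. In the double-positive cells 32 genes rose and 42 fell, each in the same direction in both experiments. Spp1, which encodes the secreted glycoprotein osteopontin, was 51.8-fold higher (log2 change 5.69 ± 0.78, limma adjusted p = 0.0309), and Il1r2, the decoy receptor for interleukin-1, was at least 25.9-fold higher. Lag3 was 29.0-fold higher (4.86 ± 0.36, limma adjusted p = 0.0114) and Tnfrsf9 15.6-fold higher (3.97 ± 0.50, limma adjusted p = 0.0228). The chromatin organizer Satb1 was 42.0-fold lower (-5.39 ± 0.63, limma adjusted p = 0.0164).

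The other genes with the highest changes were Igfbp7, an insulin-like growth factor binding protein (4.86 ± 0.39), the chemokine Ccl3 (4.27 ± 0.44), asparagine synthetase Asns (4.21 ± 0.42), Tnfrsf4, which encodes the costimulatory receptor OX40 (3.83 ± 0.40), the kinetochore gene Kntc1 (3.76 ± 0.38) and the kinesin Kif15 (3.65 ± 0.57). Others with low changes were Igfbp4 (-5.12 ± 0.45), Klhl6 (-4.41 ± 0.41), Klf2, a transcription factor of quiescent T cells (-4.22 ± 0.47), Il7r, the interleukin-7 receptor (-4.20 ± 0.49), Socs3, an inhibitor of cytokine signalling (-4.14 ± 0.42), Nsg2 (-3.73 ± 0.41), Fcgrt (-3.67 ± 0.54) and Txnip, an inhibitor of glucose uptake (-3.63 ± 0.42). Limma adjusted p was 0.0451 for Kif15 (0.0629 with the block, range 0.00836 to 0.246) and 0.0355 for Fcgrt (0.0566 with the block, range 0.00292 to 0.202), which did not pass with the experiment as a block.

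**Figure D2:**
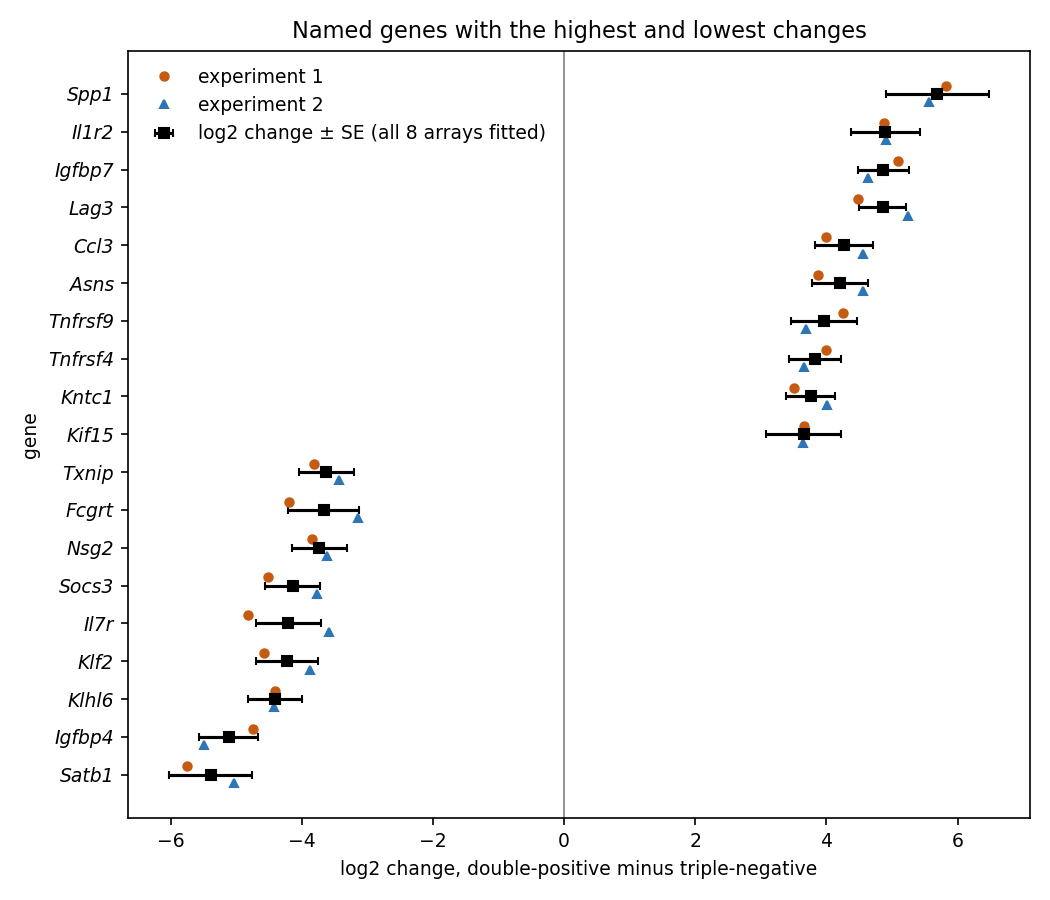
Log2 change between double-positive and triple-negative cells for the named genes with the highest and lowest changes past the threshold, as the fitted change with its standard error (squares) and as the difference within each experiment (circles and triangles). Changes run from -5.39 for Satb1 to 5.69 for Spp1. Both experiments lie on the same side of 0 for each gene, as the rule for named genes requires.

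By gene list, 20 of 22 naive and memory T cell genes were lower in double-positive cells, with a median change of -2.24. Of these 7 fell, or 16 adjusted over the list alone, among them Satb1, Igfbp4 and Klf2. The survival factor Bcl2 (-3.66 ± 0.89, and -2.45, -1.76, -1.03 and -1.07 by its other probes) and Dapl1 (-3.10 ± 0.75, limma adjusted p = 0.119, 0.0344 with the block, range 0.0224 to 0.486) did not pass. The list itself passed (camera adjusted p = 7.91e-18, range 3.02e-25 to 0.0158, adjusted p = 0.0158 with an estimated correlation). All 41 cell cycle genes were higher, with a median of 1.60. Of these 6 rose, or 21 adjusted over the list alone, among them the spindle gene Nusap1 (3.36 ± 0.38), thymidine kinase Tk1 (3.28 ± 0.38, 1.27 by another probe), the ribonucleotide reductase subunit Rrm2 (3.20 ± 0.41) and Cdc20 (2.73 ± 0.40), while Kif22 (3.96 ± 1.03) and Mcm10 (2.76 ± 1.35, 0.84 by another probe) did not pass. The cell cycle list passed with the preset correlation (camera adjusted p = 7.21e-21, range 7.74e-25 to 0.0776, adjusted p = 0.0776 with an estimated correlation). Of 18 glycolysis genes 15 were higher, with a median of 1.45. The triosephosphate isomerase Tpi1 rose (3.25 ± 0.31), 11 rose and 1 fell adjusted over the list alone, and hexokinase Hk2 (2.04 ± 0.70) and the glucose transporter Slc2a3 (2.54 ± 0.48, limma adjusted p = 0.0734, 0.0328 with the block, range 0.0295 to 0.314) did not pass. The list passed with the preset correlation (camera adjusted p = 1.58e-07, range 6.02e-10 to 0.0776, adjusted p = 0.0776 with an estimated correlation).

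Among 14 cytotoxic effector molecules none passed over all genes, 6 rose and 2 fell adjusted over the list alone, and the median was 0.91 (camera adjusted p = 0.00934, range 0.000914 to 0.197, adjusted p = 0.113 with an estimated correlation). Granzyme D, Gzmd, was at least 66.5-fold higher (limma adjusted p = 0.0530, 0.0322 with the block, range 0.000104 to 0.261) and granzyme E, Gzme, at least 8.10-fold higher (limma adjusted p = 0.0712, 0.0328 with the block, range 0.0146 to 0.306). A second Gzmd probe differed by only 0.83. Of 16 chemokines and cytokines Spp1 and Ccl3 rose, with 4 adjusted over the list alone and a median of 0.28, or 0.53 in experiment 1 and 0.08 in experiment 2 (camera adjusted p = 0.0183, range 0.000914 to 0.244, medians 0.033 to 0.43, adjusted p = 0.244 with an estimated correlation). The chemokine Ccl4 (1.91 ± 0.37) and Ifng, interferon gamma (2.49 ± 0.41, limma adjusted p = 0.0508, 0.0369 with the block, range 0.0161 to 0.334), did not pass.

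In the list of inhibitory receptors (10 genes), which also holds the ligand gene Cd274 (PD-L1), Lag3 rose and Cd274 fell (-2.28 ± 0.36), with 2 risen and 2 fallen adjusted over the list alone. Havcr2, which encodes TIM-3 (4.82 ± 1.30, limma adjusted p = 0.160), and Btla (-1.85 ± 0.34) did not pass, and camera did not call the list (median 0.59, adjusted p = 0.174). In that of costimulatory receptors (12 genes), which also holds the ligand gene Tnfsf14 (LIGHT), Tnfrsf9 and Tnfrsf4 rose, 2 rose and 1 fell adjusted over the list alone, and Tnfsf14 (-2.81 ± 0.65) and Cd2 (-0.93 ± 0.33) did not pass (median 0.09, camera adjusted p = 0.262). Of 13 exhaustion and effector transcription factors Irf8 rose (2.89 ± 0.35), 1 did so adjusted over the list alone, and Stat3 (1.47 ± 1.17) and Bhlhe40 (1.43 ± 0.48) did not pass (median 0.59, camera adjusted p = 0.0811, or 0.0338 with the block). Of 19 EGR and anergy genes Socs3 and the ubiquitin ligase gene Dtx1 (-2.87 ± 0.39) fell, with 3 adjusted over the list alone, and neuropilin-1, Nrp1 (3.88 ± 1.34), and the diacylglycerol kinase Dgka (-2.75 ± 0.58) did not pass. That list was not called (camera adjusted p = 0.146, lower), and its median of 0.06 differs in sign from its mean of -0.29.

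Of 20 interferon-stimulated genes 18 were lower, with a median of -1.29 (camera adjusted p = 1.09e-06, range 2.11e-07 to 0.0776, adjusted p = 0.0776 with an estimated correlation). Oasl2 fell (-2.45 ± 0.36, limma adjusted p = 0.0355, 0.0520 with the block, range 0.0143 to 0.279), although another probe differed by -0.39, 7 fell adjusted over the list alone, and Ifit3 (-5.23 ± 1.28) and Igtp (-2.37 ± 0.42) did not pass. Of 14 chemokine receptors and homing genes the tissue retention gene Cd69 (-3.03 ± 0.34) and the oxysterol receptor Gpr183 (-2.97 ± 0.35) fell, and 5 fell and 2 rose adjusted over the list alone. The integrins Itgae (-4.24 ± 0.95, and -4.32, -1.28 and -0.55 by its other probes, detected on 6, 3 and 3 arrays) and Itgb7 (-3.54 ± 0.63, limma adjusted p = 0.0627, 0.0335 with the block, range 0.0107 to 0.258) did not pass. The list had a median of -0.40 (camera adjusted p = 0.0331, range 0.00283 to 0.170, medians -1.47 to 0.018, adjusted p = 0.170 with an estimated correlation, and 0.0606 with the block).

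Further lists were called with no member past the test over all genes. The proteasome was higher by a median of 0.69 (camera adjusted p = 9.13e-07, range 7.09e-11 to 0.0548, adjusted p = 0.0548 with an estimated correlation). Psmd1 differed by 1.20 ± 0.38 and Psmb7 by 1.18 ± 0.51, with 0.26 and -0.29 by its other probes. Cholesterol synthesis was higher by 0.77 (camera adjusted p = 0.00722, range 0.00198 to 0.113, medians 0.14 to 0.99, adjusted p = 0.113 with an estimated correlation). Sqle differed by 2.28 ± 0.50 and Lss by 2.27 ± 1.00, and 2 rose adjusted over the list alone. Oxidative phosphorylation was higher by 0.39, or 0.57 in experiment 1 and 0.17 in experiment 2 (camera adjusted p = 0.000478, range 9.70e-10 to 0.607, medians 0.026 to 0.77, adjusted p = 0.456 with an estimated correlation). Ndufb6 differed by 1.40 ± 0.43 and Ndufb8 by 1.36 ± 0.57. Ribosomal proteins were lower, with a median of -0.39, or -0.15 in experiment 1 and -0.56 in experiment 2 (camera adjusted p = 0.000277, range 3.58e-07 to 0.454, medians -0.71 to -0.12, adjusted p = 0.454 with an estimated correlation), with Rps27 at -2.11 ± 0.64 while Rpl6 was at least 5.11-fold higher. The dissociation and stress response, which covers genes induced by tissue handling, was lower, with a median of -1.16 (camera adjusted p = 1.01e-05, range 4.76e-07 to 0.0795, adjusted p = 0.0795 with an estimated correlation). Jun differed by -2.79 ± 0.80 and Zfp36 by -2.33 ± 0.40, and 6 fell adjusted over the list alone.

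Markers of other cells differed too. The 8 melanoma cell genes had a median of 1.25, with 0.29 in experiment 1 and 2.12 in experiment 2 (camera adjusted p = 0.0331, range 0.00087 to 0.479, medians 0.078 to 2.47, adjusted p = 0.456 with an estimated correlation). Gpnmb differed by 3.23 ± 1.68 and Pmel by 2.56 ± 1.35, but their other probes by only 0.33 and 0.014. All 11 dendritic cell and class II genes were lower, with a median of -0.89 (camera adjusted p = 0.00353, range 0.00091 to 0.113, medians -1.18 to -0.29, adjusted p = 0.113 with an estimated correlation). H2-Ab1 differed by -1.43 ± 0.89 (-0.16, -0.98 and -1.19 by its other probes) and Ccr7 by -2.50 ± 0.88 (limma adjusted p = 0.274, 0.0425 with the block, range 0.0425 to 0.742). Camera did not call TCR signalling (adjusted p = 0.105), the unfolded protein response and chaperones (0.471), or the lists of regulatory T cells (0.916), CD4 T cells (0.471), NK cells (0.0811), macrophages and monocytes (0.165), neutrophils (0.471) and fibroblasts and endothelial cells (0.258).

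**Figure D3:**
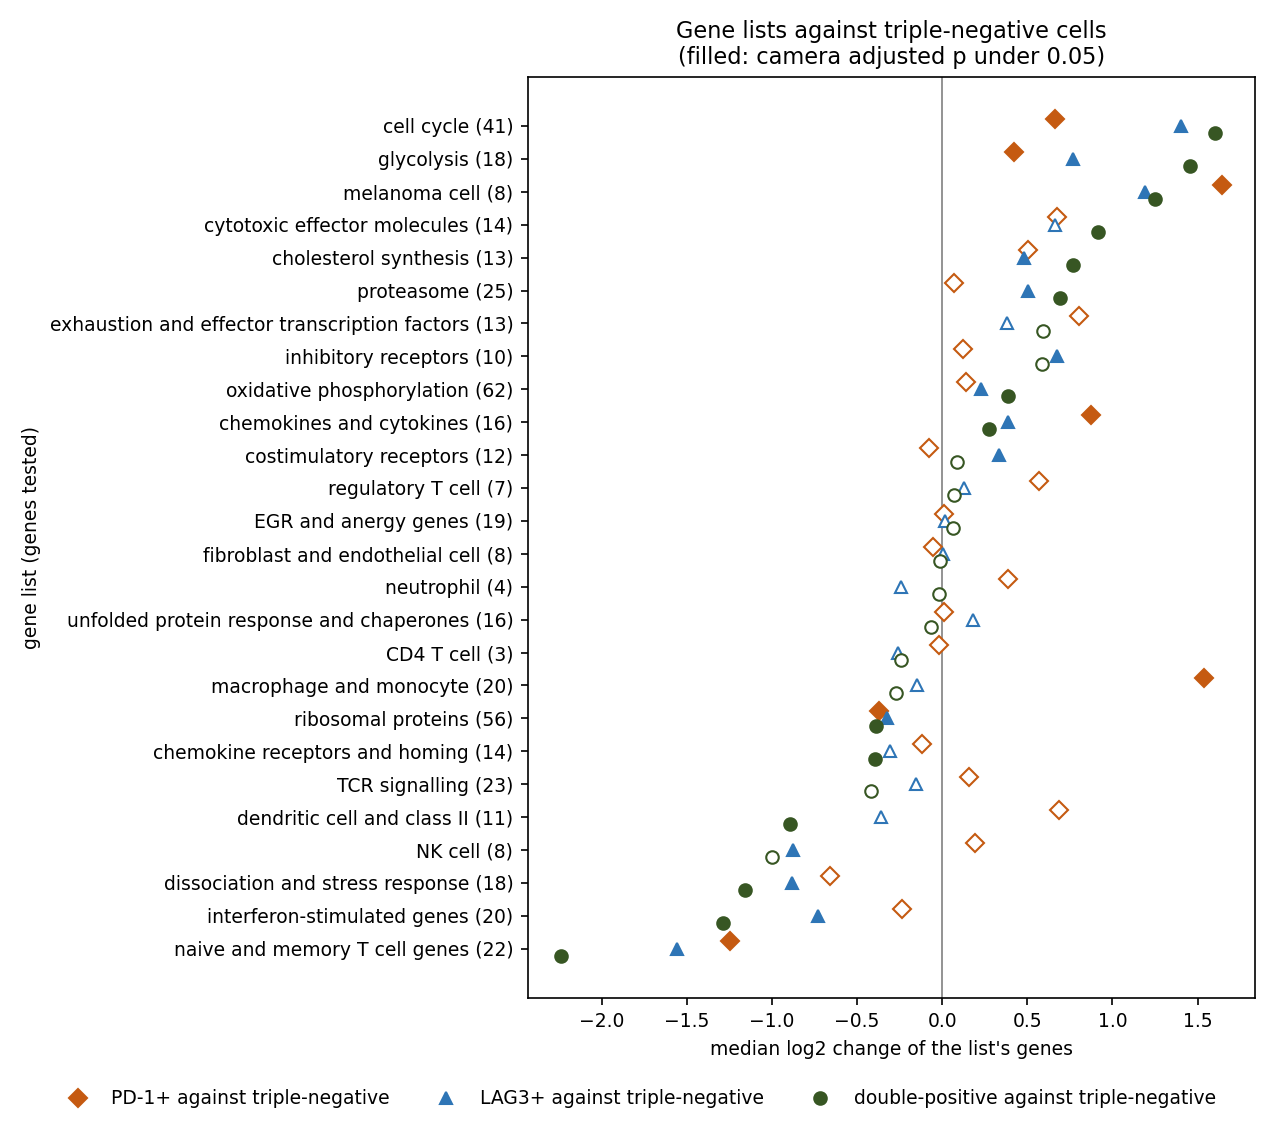
Median log2 change of each tested gene list in PD-1+ (diamonds), LAG3+ (triangles) and double-positive cells (circles) against triple-negative cells, with the number of genes tested in brackets; filled symbols passed camera with the preset correlation. Naive and memory T cell genes are lowest in double-positive cells (-2.24), and macrophage and monocyte genes lie at 1.54 in PD-1+ cells.

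In all, 74 of 7893 genes passed limma in double-positive against triple-negative cells. Without either PD-1+ array the count was 212, without either LAG3+ array 17, without triple-negative array 2 it was 1, and without triple-negative array 1 or either double-positive array it was 0 (limma, 595 to 1035 at unadjusted p under 0.05). Camera called 14 lists, 1 with an estimated correlation, 14 by fry, and 8 without triple-negative array 1.

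LAG3+ cells were compared with triple-negative cells to describe cells that carry LAG3 without 4-1BB. In LAG3+ cells 6 genes rose and 6 fell. Lag3 was 26.1-fold higher (4.71 ± 0.36, limma adjusted p = 0.0252), Igfbp7 13.8-fold higher (3.79 ± 0.39, limma adjusted p = 0.0293), Tk1 11.2-fold higher (3.49 ± 0.38, limma adjusted p = 0.0360, 1.22 by another probe) and Nusap1 10.1-fold higher (3.33 ± 0.38, limma adjusted p = 0.0389). The chaperone gene Clgn was at least 7.16-fold higher. Igfbp4 was 26.8-fold lower (-4.74 ± 0.45, limma adjusted p = 0.0252). Klra7, a receptor of the Ly49 family, was at least 13.9-fold lower, the cannabinoid receptor gene Cnr2 at least 7.14-fold lower and Tha1 at least 6.11-fold lower.

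The naive and memory T cell genes had a median change of -1.56. Of them 2 fell, among them Igfbp4, or 13 adjusted over the list alone, and Satb1 (-4.27 ± 0.63) and Klf2 (-3.68 ± 0.47) did not pass. The list itself passed (camera adjusted p = 1.47e-16, range 1.10e-23 to 0.0183, adjusted p = 0.0183 with an estimated correlation). Of 41 cell cycle genes 40 were higher, with a median of 1.40 (camera adjusted p = 7.80e-24, range 4.13e-28 to 0.0881, adjusted p = 0.0881 with an estimated correlation). Tk1 and Nusap1 rose, 24 did so adjusted over the list alone, and Kif22 (4.29 ± 1.03) and Cdc6 (3.12 ± 0.70) did not pass. The list of inhibitory receptors had a median of 0.68 (camera adjusted p = 0.0196, range 0.000398 to 0.342, medians 0.16 to 0.77, adjusted p = 0.169 with an estimated correlation). The list holds 2 genes on which the cells were sorted, Lag3 and Pdcd1, and was not called without them (median 0.39, camera adjusted p = 0.342). Of its genes Lag3 rose, 1 rose and 1 fell adjusted over the list alone, and Havcr2 (3.98 ± 1.30) and Ctla4 (1.51 ± 0.62) did not pass. The list of costimulatory receptors had a median of 0.34, or 0.17 in experiment 1 and 0.58 in experiment 2 (camera adjusted p = 0.0247, range 0.00896 to 0.219, medians 0.075 to 0.65, adjusted p = 0.219 with an estimated correlation), and the list was not called without the sorting gene Tnfrsf9 (median 0.31, camera adjusted p = 0.112). None passed over all genes and 2 rose adjusted over the list alone, with Tnfrsf9 at 2.69 ± 0.50 (1.31 by another probe) and Tnfrsf4 at 2.52 ± 0.40. Glycolysis genes were higher by a median of 0.77 (camera adjusted p = 9.81e-07, range 1.16e-08 to 0.113, adjusted p = 0.113 with an estimated correlation). Tpi1 differed by 2.34 ± 0.31 and Slc2a3 by 1.64 ± 0.48, and 7 rose and 1 fell adjusted over the list alone.

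Chemokines and cytokines were higher by a median of 0.39, or 0.93 in experiment 1 and 0.14 in experiment 2 (camera adjusted p = 0.0147, range 0.000398 to 0.219, medians 0.080 to 0.98, adjusted p = 0.219 with an estimated correlation). Spp1 differed by 3.71 ± 0.78 and Ccl3 by 2.81 ± 0.44, and 4 rose adjusted over the list alone. The proteasome was higher, with a median of 0.50 (camera adjusted p = 2.39e-05, range 2.86e-08 to 0.0873, adjusted p = 0.0873 with an estimated correlation). Psmd13 differed by 1.00 ± 0.39 and Psma4 by 0.98 ± 0.45. Cholesterol synthesis had a median of 0.48 (camera adjusted p = 0.0193, range 0.00511 to 0.169, adjusted p = 0.169 with an estimated correlation). Sqle differed by 1.56 ± 0.50 and Lss by 1.39 ± 1.00. Oxidative phosphorylation differed by a median of 0.23, with 0.52 in experiment 1 and -0.01 in experiment 2 (camera adjusted p = 0.0196, range 5.90e-08 to 0.567, medians -0.12 to 0.55, adjusted p = 0.567 with an estimated correlation). Ndufb6 differed by 1.36 ± 0.43 and Cycs by 1.04 ± 0.60, and their other probes by 0.44 and 0.13. Interferon-stimulated genes were lower, with a median of -0.73 (camera adjusted p = 0.00035, range 9.94e-05 to 0.113, medians -0.78 to -0.21, adjusted p = 0.113 with an estimated correlation). Ifit3 differed by -3.75 ± 1.28 and Oasl2 by -2.60 ± 0.36 (-0.36 by another probe), and 3 fell adjusted over the list alone. Ribosomal proteins were lower, with a median of -0.32, or -0.09 in experiment 1 and -0.46 in experiment 2 (camera adjusted p = 0.000464, range 5.58e-07 to 0.473, medians -0.57 to -0.096, adjusted p = 0.473 with an estimated correlation). Rps27 differed by -1.60 ± 0.64 and Rpl21 by 1.60 ± 0.91. The dissociation and stress response had a median of -0.88 (camera adjusted p = 0.00012, range 2.17e-06 to 0.113, adjusted p = 0.113 with an estimated correlation). Junb differed by -2.13 ± 0.48 and Zfp36 by -2.02 ± 0.40, and 3 fell adjusted over the list alone.

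The 8 NK cell genes had a median of -0.88 (camera adjusted p = 0.0196, range 0.0117 to 0.206, adjusted p = 0.206 with an estimated correlation). Klra7 fell, 1 did so adjusted over the list alone, and Klrk1 (1.66 ± 0.81, 0.14 by another probe) and Klra4 (-1.44 ± 0.58) did not pass. The melanoma cell genes had a median of 1.19, with 0.42 in experiment 1 and 1.55 in experiment 2 (camera adjusted p = 0.0271, range 0.00102 to 0.473, medians 0.058 to 1.90, adjusted p = 0.473 with an estimated correlation). Gpnmb differed by 4.03 ± 1.68 and Pmel by 2.18 ± 1.35, while their other probes were slightly lower (-0.079 and -0.26). With the experiment as a block, camera also called the exhaustion and effector transcription factors (0.0306, against 0.0805 without it), the cytotoxic effector molecules (0.0300, against 0.0519) and the dendritic cell and class II genes (0.0269, against 0.0590).

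All 12 gene calls in LAG3+ against triple-negative cells were lost with the experiment as a block, where 0 genes passed limma (898 at unadjusted p under 0.05, against 736 without it). The adjusted p of the 9 named genes then lay between 0.0513 and 0.0651, and over all alternatives between 0.00204 and 0.350. The count was 48 without either PD-1+ array and 0 without any other single array (limma, 474 to 808 at unadjusted p under 0.05). Camera called 14 lists, 1 with an estimated correlation, 7 by fry, and 9 without triple-negative array 1 or 2.

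PD-1+ cells were compared with triple-negative cells to describe cells that carry PD-1 without 4-1BB or LAG3. In PD-1+ cells 18 genes rose and 24 fell. The highest were histone genes, whose products package DNA: H3c6 was 32.7-fold higher (5.03 ± 0.72, limma adjusted p = 0.0487), H2ac22 20.9-fold higher (4.39 ± 0.41, limma adjusted p = 0.0198), H2ac10 20.6-fold higher (4.36 ± 0.50) and H3c1 20.3-fold higher (4.34 ± 0.52). Lag3 was 18.1-fold higher (4.18 ± 0.36, limma adjusted p = 0.0198) in cells sorted as lacking surface LAG3. Igfbp4 was 24.6-fold lower (-4.62 ± 0.45, limma adjusted p = 0.0198), and the ubiquitin ligase gene Pja1 was at least 15.9-fold lower.

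Ormdl3, a regulator of sphingolipid synthesis, was at least 11.9-fold lower (limma adjusted p = 0.0487, 0.0628 with the block, range 0.0351 to 0.319). Ccdc174 was at least 11-fold lower (0.0565 with the block, range 0.0351 to 0.319) and Entpd4 at least 9.23-fold lower (0.0563 with the block, range 0.0328 to 0.319). Histones made up 11 of the 18 genes that rose, against 40 of the 7893 genes tested (Fisher's exact test, two-sided, p = 3.90e-22). This family was chosen after its values were seen, and near-identical histone genes can share probe signal, so its members are not independent. The median change of the 40 genes was 2.56, with 2.93 in experiment 1 and 2.28 in experiment 2, and between 1.42 and 2.69 under the other scalings.

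Macrophage and monocyte genes were higher on the same arrays, 18 of 20, with a median of 1.54, or 0.85 in experiment 1 and 1.61 in experiment 2 (camera adjusted p = 9.48e-08, range 1.13e-10 to 0.446, adjusted p = 0.446 with an estimated correlation). The chitinase-like gene Chil3 rose (at least 4.78-fold higher), 10 rose adjusted over the list alone, and arginase, Arg1 (at least 9.54-fold higher, limma adjusted p = 0.0585, 0.0499 with the block, range 0.0247 to 0.319), and Sirpa (2.84 ± 0.68) did not pass. The melanoma cell genes had a median of 1.64, with 0.49 in experiment 1 and 2.67 in experiment 2 (camera adjusted p = 0.00376, range 0.000751 to 0.474, medians 0.13 to 3.01, adjusted p = 0.474 with an estimated correlation). The pigment cell gene Pmel averaged 9.61 ± 1.22 (SD, n = 2) in PD-1+ and 5.05 ± 0.14 (SD, n = 2) in triple-negative cells, a change of 4.56 ± 1.35, and Gpnmb differed by 3.67 ± 1.68. Their other probes differed by only 0.34 and -0.030.

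The naive and memory T cell genes had a median of -1.24 in PD-1+ cells (camera adjusted p = 6.26e-06, range 1.17e-10 to 0.143, adjusted p = 0.143 with an estimated correlation). Igfbp4 fell, 8 fell adjusted over the list alone, and Satb1 (-2.38 ± 0.63) and Klf2 (-2.34 ± 0.47) did not pass. The cell cycle genes had a median of 0.66, with 0.97 in experiment 1 and 0.05 in experiment 2 (camera adjusted p = 2.35e-06, range 2.34e-07 to 0.446, medians 0.034 to 1.40, adjusted p = 0.446 with an estimated correlation). Rrm2 rose (3.08 ± 0.41, limma adjusted p = 0.0445, 0.0530 with the block, range 0.0335 to 0.319), 7 rose adjusted over the list alone, and Kif22 (4.24 ± 1.03) and Cdc20 (2.62 ± 0.40) did not pass. Chemokines and cytokines were higher by a median of 0.88 (camera adjusted p = 0.00244, range 0.000556 to 0.446, medians 0.040 to 1.54, adjusted p = 0.446 with an estimated correlation), with 4 risen adjusted over the list alone, interleukin-10, Il10, at least 6.37-fold higher and Spp1 at 2.48 ± 0.78, neither past the test. Glycolysis genes had a median of 0.42 (camera adjusted p = 0.0157, range 0.000545 to 0.509, adjusted p = 0.460 with an estimated correlation), with 2 risen and 1 fallen adjusted over the list alone, Tpi1 at 1.72 ± 0.31 and Pdk1 at least 2.82-fold lower. Ribosomal proteins had a median of -0.37 (camera adjusted p = 0.00376, range 5.80e-08 to 0.622, medians -0.65 to -0.099, adjusted p = 0.622 with an estimated correlation). Rplp0 differed by -2.13 ± 1.31 and Rpl4 by -2.11 ± 0.39.

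In the list of inhibitory receptors Lag3 rose, 1 rose and 1 fell adjusted over the list alone, and Havcr2 (1.84 ± 1.30, -0.35 without PD-1+ array 1) and Cd274 (-1.50 ± 0.36) did not pass (median 0.12, camera adjusted p = 0.466). In that of costimulatory receptors no gene passed over all genes and 2 rose adjusted over the list alone, with Tnfrsf9 at 2.47 ± 0.50 and Tnfrsf4 at 1.61 ± 0.40. That list was not called (camera adjusted p = 0.694, higher), and its median of -0.08 differs in sign from its mean of 0.24. With the experiment as a block, camera also called the exhaustion and effector transcription factors (0.0369, against 0.0926 without it).

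In all, 42 genes passed limma in PD-1+ against triple-negative cells, 27 of them not detected on either array of their lower population. The 18 higher and 24 lower genes became 26 and 4 with median scaling, 20 and 10 with another background correction, and 25 and 13 without background correction. Median scaling moved the median of all genes by 0.74 in this comparison. The folds given as "at least" for the lower genes therefore depend on the scaling. The count was 295 without PD-1+ array 1, 127 without PD-1+ array 2, and 0 without any other single array (limma, 927 to 994 at unadjusted p under 0.05), or 28 with the experiment as a block. Camera called 7 lists, 0 with an estimated correlation (1 at unadjusted p under 0.05), 1 by fry, and 4 without PD-1+ array 1.

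Double-positive and LAG3+ cells differ in surface 4-1BB, and their comparison asks what goes with that receptor among cells that carry LAG3. No gene passed limma (0 of 7893, with 208 at unadjusted p under 0.05), nor with the experiment as a block (0, with 261 at unadjusted p under 0.05). Even Tnfrsf9, the gene of 4-1BB, differed by 1.27 (1.93 by another probe) and did not pass. In the simulations of double-positive against triple-negative cells, limma recovered only 0.507% of log2 changes of 1 and 16.6% of 2. The 0 calls therefore do not show that the 2 populations are alike. The 3 genes with the smallest p were Pes1, a ribosome biogenesis gene (at least 4.98-fold higher, limma adjusted p = 0.845), the semaphorin Sema4f (-2.38 ± 0.34, limma adjusted p = 0.845) and Lgi2 (at least 3.01-fold higher, limma adjusted p = 0.969). Naive and memory T cell genes were lower in double-positive cells, with a median of -0.50 (camera adjusted p = 4.19e-06, range 2.44e-07 to 0.197, adjusted p = 0.117 with an estimated correlation). Dapl1 differed by -1.60 ± 0.75, and 1 fell adjusted over the list alone. Chemokine receptors and homing genes were lower too, with a median of -0.18, or -0.41 in experiment 1 and -0.22 in experiment 2 (camera adjusted p = 0.000593, range 1.34e-06 to 0.160, medians -1.10 to -0.040, adjusted p = 0.160 with an estimated correlation). Itgb7 differed by -1.81 ± 0.63 and the chemokine receptor Cxcr3 by -1.79 ± 0.45.

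Interferon-stimulated genes were lower, with a median of -0.36, or -0.12 in experiment 1 and -0.53 in experiment 2 (camera adjusted p = 0.00701, range 0.00292 to 0.382, adjusted p = 0.317 with an estimated correlation), with Rsad2 at -1.28 ± 0.99 and Ifit3 at -1.47 ± 1.28, or 0.62 without LAG3+ array 2. Glycolysis genes were higher by a median of 0.33 (camera adjusted p = 0.0123, range 0.000107 to 0.382, adjusted p = 0.317 with an estimated correlation). Eno3 differed by 1.24 ± 0.91 and Slc2a3 by 0.90 ± 0.48. The list of inhibitory receptors had a median of 0.05 and a mean of -0.20 and was not called (camera adjusted p = 0.163, lower). Btla differed by -1.59 ± 0.34 and Cd274 by -0.91 ± 0.36, and 1 fell adjusted over the list alone. That of costimulatory receptors had a median of -0.13 (camera adjusted p = 0.502). Tnfsf14 differed by -1.43 ± 0.65 and Tnfrsf4 by 1.31 ± 0.40. With the experiment as a block, camera also called the cytotoxic effector molecules (0.0339, against 0.0725 without it), oxidative phosphorylation (0.0293, against 0.0586), the proteasome (0.0409, against 0.0725) and the dendritic cell and class II genes (0.0293, against 0.0725). It called 4 lists without the block, 8 with it, 7 without double-positive array 2, 0 with an estimated correlation and 0 by fry (3 and 4 at unadjusted p under 0.05).

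Double-positive and PD-1+ cells were compared to set cells with 4-1BB and LAG3 against cells with PD-1 alone of the 3 receptors. In double-positive cells Igfbp7 was at least 25.7-fold higher (limma adjusted p = 0.0161) and Clgn at least 4.74-fold higher (limma adjusted p = 0.0321, 0.0543 with the block, range 0.00234 to 0.290). Cyp4f18, a cytochrome P450, was at least 11.8-fold lower (limma adjusted p = 0.0161).

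Macrophage and monocyte genes were lower in double-positive than in PD-1+ cells, with a median of -1.66, or -0.53 in experiment 1 and -2.20 in experiment 2 (camera adjusted p = 6.35e-10, range 1.20e-11 to 0.157, medians -2.20 to -0.45, adjusted p = 0.157 with an estimated correlation). None passed over all genes and 8 fell adjusted over the list alone. The lysozyme gene Lyz1 differed by -4.37 ± 0.68 and Sirpa by -3.73 ± 0.68. Dendritic cell and class II genes were lower, with a median of -1.41, or -0.69 in experiment 1 and -2.25 in experiment 2 (camera adjusted p = 0.000136, range 5.66e-05 to 0.143, medians -2.07 to -0.21, adjusted p = 0.143 with an estimated correlation). H2-Aa differed by -2.58 ± 0.55 and Cd74, the invariant chain of MHC class II, by -2.53 ± 0.46, and 2 fell adjusted over the list alone. NK cell genes were lower, with a median of -1.13, or -0.09 in experiment 1 and -1.51 in experiment 2 (camera adjusted p = 0.0134, range 0.00360 to 0.358, medians -1.65 to -0.16, adjusted p = 0.181 with an estimated correlation), with 1 fallen adjusted over the list alone, Klra7 at -1.85 ± 0.38 and Tyrobp at least 2.85-fold lower. Naive and memory T cell genes were lower, with a median of -1.07 (camera adjusted p = 5.17e-08, range 3.27e-08 to 0.0760, adjusted p = 0.0760 with an estimated correlation). Of them 1 fell, or 7 adjusted over the list alone, and Satb1 (-3.01 ± 0.63) and Nsg2 (-2.18 ± 0.41) did not pass.

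Cell cycle genes were higher by a median of 0.73 (camera adjusted p = 2.91e-06, range 4.43e-08 to 0.199, medians 0.18 to 1.03, adjusted p = 0.199 with an estimated correlation), with 2 risen adjusted over the list alone, Prc1 at 2.79 ± 0.81 and Spag5 at least 3.35-fold higher. Glycolysis genes were higher by 0.69 (camera adjusted p = 0.000726, range 2.61e-06 to 0.181, adjusted p = 0.181 with an estimated correlation). Tpi1 differed by 1.53 ± 0.31 and Eno3 by 1.5 ± 0.91, and 4 rose adjusted over the list alone. Oxidative phosphorylation was higher by 0.33 (camera adjusted p = 0.00771, range 4.01e-07 to 0.614, adjusted p = 0.614 with an estimated correlation). Cox5a differed by 1.62 ± 0.37 and Ndufa8 by 1.15 ± 0.46. The proteasome had a median of 0.48 (camera adjusted p = 0.000556, range 4.01e-07 to 0.143, adjusted p = 0.143 with an estimated correlation). Psmc4 differed by 1.49 ± 0.37 and Psmd1 by 1.41 ± 0.38. Chemokine receptors and homing genes were lower, with a median of -0.88 (camera adjusted p = 0.00321, range 8.28e-05 to 0.157, medians -1.51 to -0.28, adjusted p = 0.157 with an estimated correlation). Itgb7 differed by -2.73 ± 0.63 and Cxcr3 by -2.61 ± 0.45, and 5 fell and 1 rose adjusted over the list alone. Interferon-stimulated genes were lower too, with a median of -1.11, or -0.25 in experiment 1 and -0.87 in experiment 2 (camera adjusted p = 0.00103, range 0.000438 to 0.157, medians -1.42 to -0.18, adjusted p = 0.157 with an estimated correlation). Ifit3 differed by -2.76 ± 1.28 and Zbp1 by -2.75 ± 0.92. The dissociation and stress response had a median of -0.64 (camera adjusted p = 0.00443, range 0.00103 to 0.236, adjusted p = 0.181 with an estimated correlation). Jun differed by -1.87 ± 0.80 and Ier3 by -1.49 ± 0.78. The receptor lists were not called (camera adjusted p = 0.781 for inhibitory and 0.409 for costimulatory receptors). Havcr2 differed by 2.98 ± 1.30, Btla by -1.37 ± 0.34, Tnfsf14 by -3.18 ± 0.65 and Tnfrsf4 by 2.22 ± 0.40, none past the test over all genes.

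The 4 genes called between double-positive and PD-1+ cells, 2 in each direction, became 3 higher and 16 lower with median scaling and 3 higher and 5 lower with the authors' normalized values. The count was 378 without PD-1+ array 1, 47 without PD-1+ array 2 and 0 without any other single array (limma, 681 to 1133 at unadjusted p under 0.05). Camera called 11 lists, 0 with an estimated correlation (6 at unadjusted p under 0.05) and 11 by fry.

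LAG3+ and PD-1+ cells were compared to set cells with LAG3 against cells with PD-1 alone of the 3 receptors. In LAG3+ cells Igfbp7 was at least 12.2-fold higher (limma adjusted p = 0.0316), the taurine transporter gene Slc6a6 at least 11.7-fold higher (limma adjusted p = 0.0478), Ccdc181 at least 8.39-fold higher and Clgn at least 5.47-fold higher. Cyp4f18 was at least 11.7-fold lower (limma adjusted p = 0.0316) and Chil3 at least 4.83-fold lower (limma adjusted p = 0.0478). Macrophage and monocyte genes were lower in LAG3+ cells, with a median of -1.64, or -0.50 in experiment 1 and -1.94 in experiment 2 (camera adjusted p = 2.60e-09, range 4.24e-11 to 0.207, medians -2.03 to -0.32, adjusted p = 0.207 with an estimated correlation). Chil3 fell, 9 fell adjusted over the list alone, and Sirpa (at least 12.7-fold lower) and Lyz1 (-2.70 ± 0.68) did not pass.

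Dendritic cell and class II genes were lower, with a median of -0.98, or -0.23 in experiment 1 and -1.85 in experiment 2 (camera adjusted p = 0.00310, range 0.00121 to 0.207, medians -1.50 to -0.062, adjusted p = 0.207 with an estimated correlation). Cd74 differed by -2.23 ± 0.46 and H2-Aa by -2.05 ± 0.55, and 2 fell adjusted over the list alone. NK cell genes were lower, with a median of -1.15, or -0.39 in experiment 1 and -1.25 in experiment 2 (camera adjusted p = 0.00524, range 0.00219 to 0.305, medians -1.47 to -0.32, adjusted p = 0.207 with an estimated correlation), with 2 fallen adjusted over the list alone, Klra7 at least 5.58-fold lower and Fcer1g at -2.15 ± 0.59. Naive and memory T cell genes were lower, with a median of -0.64 (camera adjusted p = 0.000474, range 0.000221 to 0.207, adjusted p = 0.207 with an estimated correlation). Satb1 differed by -1.88 ± 0.63, and 1 fell adjusted over the list alone. Cell cycle genes were higher by a median of 0.65 (camera adjusted p = 1.01e-05, range 1.33e-06 to 0.413, medians 0.16 to 0.95, adjusted p = 0.413 with an estimated correlation). Cdc6 differed by 2.52 ± 0.70 and Prc1 by 2.37 ± 0.81. The proteasome had a median of 0.32 (camera adjusted p = 0.0173, range 3.74e-05 to 0.207, adjusted p = 0.207 with an estimated correlation). Psma4 differed by 1.30 ± 0.45 and Psmc4 by 1.09 ± 0.37. The receptor lists were not called (camera adjusted p = 0.191 for inhibitory and 0.191 for costimulatory receptors). Havcr2 differed by 2.13 ± 1.30, or -0.06 without PD-1+ array 2, Ctla4 by 1.38 ± 0.62, Tnfsf14 by -1.75 ± 0.65, Tnfrsf18 by 1.37 ± 0.39 and Tnfrsf9 by 0.22 ± 0.50 (-0.39 by another probe), none past the test.

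All 6 genes called between LAG3+ and PD-1+ cells were undetected on both arrays of their lower population. With the experiment as a block 0 genes passed limma (1122 at unadjusted p under 0.05, against 908 without it). The adjusted p of these genes then lay between 0.0741 and 0.0993, and between 0.00100 and 0.475 over all alternatives. The 4 higher and 2 lower genes became 4 and 1 with the authors' normalized values, and 1 and 1 with another background correction or none. The count was 165 without PD-1+ array 1, 31 without PD-1+ array 2 and 0 without any other single array (limma, 588 to 917 at unadjusted p under 0.05). Camera called 6 lists, 0 with an estimated correlation and 0 by fry (5 and 10 at unadjusted p under 0.05), and 3 without PD-1+ array 2.

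The calls of the comparisons against triple-negative cells, made without the block, overlapped. Double-positive and LAG3+ cells shared 6 higher genes (Clgn, Igfbp7, Lag3, Nusap1, Smpdl3b and Tk1) and 6 lower genes (among them Cnr2, Igfbp4, Il11ra1, Klra7 and Tha1), which is every gene called in LAG3+ cells. Independent lists of these sizes would share 0.0243 and 0.0319 genes. In 100 simulations without any effect, the genes with the smallest p, taken in the same numbers, shared 1.84 higher and 2 lower genes on average, at most 4 and 5. Double-positive and PD-1+ cells shared 2 higher genes, Lag3 and Rrm2, and 8 lower genes, Cnr2, Gpr146, Igfbp4, Il11ra1, Nedd4l, Oasl2 (-2.76 in PD-1+ cells, -0.35 by another probe), Sema4f and Tha1 (0.0730 and 0.128 for independent lists, 4.44 and 6.02 on average and at most 11 and 11 in the simulations). LAG3+ and PD-1+ cells shared Lag3 and 4 lower genes, Cnr2, Igfbp4, Il11ra1 and Tha1 (0.0137 and 0.0182 for independent lists, 1.59 and 1.69 on average and at most 5 and 5 in the simulations). The 2 triple-negative arrays are common to all 3 comparisons and too few to divide. The overlaps with PD-1+ cells lay within those of the simulated lists of the same sizes. Those lists were filled by smallest p whether or not a gene passed. Simulated genes past the threshold shared at most 1 gene between double-positive and LAG3+ cells, and 0 between either of these and PD-1+ cells. Part of each overlap may come from the shared arrays, and how much is not settled by these simulations. With the block LAG3+ cells had 0 calls, so both overlaps with them were empty, and double-positive and PD-1+ cells shared partly other genes, Lag3 and S100a6 among the higher and Cnr2, Gadd45g, Gzmm, Igfbp4, Il11ra1, Sema4f and Tha1 among the lower. Rrm2, Gpr146, Nedd4l and Oasl2 were no longer shared. The simulations were made without the block. Whether a gene called in one population and not in another differs between them was tested only by the direct comparisons above.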

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

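The fit without both PD-1+ arrays and the lists without the genes of the sorting markers were chosen only after the results were seen, and all other settings were fixed earlier. The 227 gene changes of the report were refitted under each alternative setting. Of the values this gave, 3601 kept their direction and their side of the threshold, 506 lost a call, 187 gained one and 28 turned sign. For the 56 list calls, 1039 values kept the call, 161 lost it and 1 turned direction. A random block was not run for lists, and probes tested separately gave counts only. With the fixed block 80 genes passed limma in double-positive against triple-negative cells (57 of the 74 kept), 28 in PD-1+ against triple-negative cells (21 of the 42) and 5 in double-positive against PD-1+ cells (3 of the 4). Myl12a and Tgm2 were gained in the last (both at adjusted p = 0.0426) and are named for that, after their values were seen. Of the genes and lists in the comparisons, the block changed no call other than those given there. The array signals limit what can be seen of dim genes. In double-positive, LAG3+ and PD-1+ cells against triple-negative cells, 9 of 74, 5 of 12 and 27 of 42 called genes were undetected on both arrays of their lower population, so their changes are bounds. Unless a reason is given, the cause of a change named here was not tested.

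In double-positive against triple-negative cells the 74 called genes became 113 with another background correction, 117 with median scaling (56 shared), 42 without the detection filter, which tests more genes, 116 with the experiment as a random block, 229 with array weights and 212 without both PD-1+ arrays. Leaving out single arrays gave 0 to 212. The 12 of LAG3+ against triple-negative cells became 22 with another background correction, 21 without one, 33 with median scaling (8 shared), 30 for genes detected on all arrays, 66 with array weights, 48 without both PD-1+ arrays, and 0 with the block or with only the 4 arrays compared (limma, 898 and 924 at unadjusted p under 0.05). Leaving out single arrays gave 0 to 48.

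The 42 of PD-1+ against triple-negative cells became 26 for genes detected on all arrays, 85 with a random block, and 0 with array weights or only the 4 arrays compared (limma, 742 and 742 at unadjusted p under 0.05), and 0 to 295 with single arrays left out. Double-positive against LAG3+ cells had 1 call without the detection filter, Lgi2, and 0 in every other fit, single arrays left out included (limma, 68 to 432 at unadjusted p under 0.05).

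For double-positive against PD-1+ cells the 4 calls became 8 without background correction, 19 with median scaling, 8 with the authors' values, 26 without the detection filter, 40 for genes detected on all arrays (1 shared), 14 with probes tested separately, 82 with a random block and 0 with only the 4 arrays compared (limma, 942 at unadjusted p under 0.05), and 0 to 378 with single arrays left out. For LAG3+ against PD-1+ cells the 6 became 2 with another background correction or none, and 0 with median scaling, detection on all arrays, the block, a trended and robust prior, array weights or only the 4 arrays compared (limma, 479, 323, 1122, 834, 655 and 706 at unadjusted p under 0.05). Single arrays left out gave 0 to 165. The reasons partly lie in how the fits are made. A fit of 4 arrays has fewer residual degrees of freedom, and a population left with 1 array adds nothing to the pooled spread and is assumed to vary like the others, so leaving out a PD-1+ array, where replicates correlated least, raised the counts.

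With an estimated correlation camera called 1 list in double-positive and 1 in LAG3+ against triple-negative cells, the naive and memory T cell genes in both, and 0 in PD-1+ against triple-negative cells and in double-positive against LAG3+, double-positive against PD-1+ and LAG3+ against PD-1+ cells (1, 3, 6 and 5 at unadjusted p under 0.05). Fry called 7 in LAG3+ and 1 in PD-1+ against triple-negative cells, and 0 in double-positive against LAG3+ and LAG3+ against PD-1+ cells (4 and 10). Camera called 10 lists with median scaling and 8 with the block in double-positive against LAG3+ cells, and 8 in LAG3+ against triple-negative cells for genes detected on all arrays. Over single arrays left out the called lists ranged 8 to 14 for double-positive, 9 to 15 for LAG3+ and 4 to 7 for PD-1+ against triple-negative cells, 3 to 7 for double-positive against LAG3+, 11 to 12 for double-positive against PD-1+ and 3 to 7 for LAG3+ against PD-1+ cells.

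Median scaling moved the median of all genes by -0.094, 0.092 and 0.74 in double-positive, LAG3+ and PD-1+ against triple-negative cells, and by -0.18, -0.87 and -0.70 in double-positive against LAG3+, double-positive against PD-1+ and LAG3+ against PD-1+ cells. It ended the list calls of chemokine receptors and homing genes (median -1.34 from -0.88, adjusted p = 0.0683, range 8.28e-05 to 0.157), the dissociation and stress response (median -0.89 from -0.64, adjusted p = 0.236, range 0.00103 to 0.236) and NK cells (median -1.65 from -1.13, adjusted p = 0.0703, range 0.00360 to 0.358) in double-positive against PD-1+ cells. In LAG3+ against triple-negative cells it ended those of costimulatory receptors (median 0.33 from 0.34, adjusted p = 0.0758, range 0.00896 to 0.219) and oxidative phosphorylation (median 0.21 from 0.23, adjusted p = 0.212, range 5.90e-08 to 0.567). The dendritic cell list was lost in LAG3+ against PD-1+ cells (median -1.15 from -0.98, adjusted p = 0.0693, range 0.00121 to 0.207) and glycolysis in PD-1+ against triple-negative cells (median 1.09 from 0.42, adjusted p = 0.191, range 0.000545 to 0.509). Camera compares a list with the other genes, so a call can end while its median stays or grows. Without the detection filter, which adds undetected genes to the lists, those of dendritic cells (median -0.062 from -0.98, adjusted p = 0.195) and NK cells (median -0.38 from -1.15, adjusted p = 0.0509) were lost in LAG3+ against PD-1+ cells, and NK cells (median -0.18 from -1.13, adjusted p = 0.105) in double-positive against PD-1+ cells. For genes detected on all arrays, chemokines and cytokines (median 0.033 from 0.28, adjusted p = 0.232) and cytotoxic effector molecules (median 0.91 from 0.91, adjusted p = 0.197) were lost in double-positive against triple-negative cells. In LAG3+ against triple-negative cells chemokines and cytokines (median 0.55 from 0.39, adjusted p = 0.0903), cholesterol synthesis (median 0.77 from 0.48, adjusted p = 0.0768), interferon-stimulated genes (median -0.61 from -0.73, adjusted p = 0.0829) and oxidative phosphorylation (median 0.23 from 0.23, adjusted p = 0.0829) were lost. Without the genes of the sorting markers the inhibitory (0.342) and costimulatory receptors (0.112) were lost in LAG3+ against triple-negative cells. The melanoma list was lost with another background correction or none in double-positive (0.0716 and 0.0921, range 0.00087 to 0.479) and LAG3+ against triple-negative cells (0.0672 and 0.0869, range 0.00102 to 0.473). The NK cell list was lost without background correction in LAG3+ against triple-negative cells (0.0540, range 0.0117 to 0.206).

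Signs turned in genes that passed no test in the comparison. With median scaling, Cd3e differed by -0.048 in double-positive against triple-negative cells and Cd8b1 by -0.071 in LAG3+ against triple-negative cells. Cd4 differed by 1.05 in PD-1+ against triple-negative cells, and Pdcd1 by -0.11 in double-positive against LAG3+ and -0.90 in double-positive against PD-1+ cells. In LAG3+ against PD-1+ cells Cd3e differed by -0.14, Cd4 by -1.16, Cd8b1 by -0.41 and Pdcd1 by -0.79. Over single arrays left out, Cd3e ranged -0.064 to 0.28 and Cd8b1 -0.34 to 0.079 in double-positive, Cd8b1 -0.030 to 0.39 in LAG3+, and Cd8b1 -0.034 to 0.39 and Havcr2 -0.35 to 4.04 in PD-1+ against triple-negative cells. In double-positive against LAG3+ cells Ifit3 ranged -3.56 to 0.62, Lag3 -0.069 to 0.37 and Pdcd1 -0.036 to 0.29, and in double-positive against PD-1+ cells Pdcd1 -0.29 to 0.83. In LAG3+ against PD-1+ cells Cd3e ranged -0.17 to 0.23, Cd4 -0.029 to 0.22, Cd8b1 -0.064 to 0.073, Havcr2 -0.061 to 4.33, Pdcd1 -0.42 to 0.70 and Tnfrsf9 -0.53 to 0.97. The oxidative phosphorylation median in LAG3+ against triple-negative cells ranged -0.12 to 0.55, lowest without triple-negative array 1. That of chemokine receptors and homing genes in double-positive against triple-negative cells was 0.018 without the detection filter, where camera did not call the list (adjusted p = 0.122, range 0.00283 to 0.170).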

Other observations

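The test on other scalings of the histone genes and the 2 tests on Lag3 were chosen only after the results were seen. The random-list test on macrophage genes and the test on cycling cells were written before their values were seen, for patterns that had been seen. The transcription factor gene Egr2, singled out after its values were seen, averaged 6.10 in triple-negative, 7.30 in PD-1+, 5.81 in LAG3+ and 4.87 in double-positive cells. It did not pass in any comparison, and the change between double-positive and PD-1+ cells was -2.43 ± 0.40, limma adjusted p = 0.0685. The lists of B cells, red blood cells and gamma-delta T cells had 2 tested genes each and were not tested as lists. The B cell gene Cd79b averaged 6.18 in triple-negative, 7.98 in PD-1+, 5.69 in LAG3+ and 4.21 in double-positive cells (smallest limma adjusted p over the comparisons, 0.0678). In the same order Cd22 averaged 4.88, 4.52, 4.26 and 4.12 (0.377). The globin gene Hba-a1 averaged 4.48, 4.59, 4.36 and 4.2 (0.697), and Hbb-bt 4.39, 4.16, 4.44 and 4.19 (0.760). The gamma-delta T cell gene Cd163l1 averaged 6.33, 4.23, 4.28 and 4.2 (0.309), and the cytokine gene Il17a 4.52, 5.16, 4.56 and 4.27 (0.440).

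The 20 macrophage and monocyte genes were higher on the PD-1+ arrays by a median of 1.59 over the mean of the 6 other arrays. Of these, 2 (Fcer1g and Tyrobp) are also in another list, and 12 were detected on both triple-negative arrays. The median of 1.59 lay at percentile 100 of 10000 random lists matched on level (median of their medians 0.04). Genes at these levels thus did not rise in general on the dim PD-1+ arrays. The list was taken up for its high values, and the random genes were drawn independently. The percentile therefore does not decide on normalization of these arrays as the cause. Of 7 abundant macrophage transcripts, 6 of them members of the list, 4 were detected on both PD-1+ arrays, and 3 of these were higher there than on every other array: Lyz2 at 7.34 and 9.16 on PD-1+ arrays 1 and 2 (4.55 to 6.69 on the others), Apoe at 6.18 and 6.10 and Cd74, which is outside the list, at 8.53 and 8.51. Ctss was highest on the PD-1+ array within each experiment but not above every other array. It lay at 5.43 (4.59 to 4.84 on the others) in experiment 1 and 6.11 (5.18 to 5.57) in experiment 2. C1qa and C1qb were detected on 1 array, PD-1+ array 2, and C1qc on 0 of 8. These values do not decide the source. RNA from macrophages or monocytes, and expression of these genes by PD-1+ T cells, a difference between the sorted populations, were not tested and stay open. The cells were stained for CD8a and CD3, and whether the sort left out all macrophages and monocytes was not tested.

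The 40 replication-dependent histone genes were higher in PD-1+ than in triple-negative cells by a median of 2.56 (quartiles 1.05 and 3.90), against 0.63 in double-positive and 0.13 in LAG3+ cells. Normalization of the dim arrays as the whole cause is argued against: with 4 other background corrections or scalings the median, less the median of all genes, stayed at 1.43 or more (lower quartile at least 0.43). A larger share of cycling cells as the whole cause is argued against too. In PD-1+ cells 37 of 40 histone genes were higher than the mean of LAG3+ and double-positive cells, by a median of 1.75 (quartiles 0.81 and 2.72). The cell cycle list, in contrast, was higher in LAG3+ and double-positive than in PD-1+ cells, by medians of 0.65 and 0.73. These 2 list calls were lost with an estimated correlation (camera adjusted p = 0.413 and 0.199). Against triple-negative cells, however, the cell cycle list was higher in PD-1+ cells, by a median of 0.66 (camera adjusted p = 2.35e-06, 0.446 with an estimated correlation). A partial contribution of cycling cells therefore stays open. Most of these transcripts lack a poly(A) tail, so RNA quality or the amplification, whose method is not given in the sources used here, may differ between sorts, which was not tested. A biological difference between the sorted populations was not tested either, and near-identical genes can share probe signal.

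Lag3 transcript was higher by 4.18 ± 0.36 in PD-1+ than in triple-negative cells, although both were sorted as lacking surface LAG3. Background correction and normalization as the cause are argued against, since the change stayed at 2.41 or more with 4 other corrections or scalings. LAG3+ cells carried into the PD-1+ sort may be the source, and as the source of all Lag3 signal they cannot be told apart from Lag3 transcript of the PD-1+ cells. Lag3 would need a share of 0.683 such cells as measured, or 0.400 when lowered by 2 standard errors. The 99 genes at least 2 (log2) higher in LAG3+ than in triple-negative cells at a level of at least 7 had a median implied share of 0.364. The share was under 0.333 times that of Lag3 for 35 of them, and 7 were undetected on both PD-1+ arrays. Of the 99 genes 24 (24.2%) lay over 2 standard errors below the level implied by Lag3 as measured, and 11 (11.1%) below that implied by the lowered Lag3, between bounds of 10% and 20% that were set after the distribution was seen. The spread of Lag3 itself keeps this open, and genes chosen for high values in LAG3+ cells can have implied shares that are too low. PD-1+ cells may express many of these genes themselves, which keeps a smaller share of carried cells open too. Transcript without surface protein, a biological explanation, was not tested and stays open.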
